A study of Zea mays with 4 samples.

How the data were processed

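RNA from 4 maize (Zea mays) samples was measured on the Affymetrix Maize Genome array, on which each probe set is a group of short oligonucleotides for 1 transcript cluster. Per the labels, 2 arrays carried RNA of the inbred line F98902, described as poorly digestible, and 2 carried RNA of the inbred line Cm484, described as well digestible. The labels number the samples of each line 1 and 2 and do not say whether they came from separate plants, so p-values measure only the spread between these samples, which may be technical. The labels' protocols disagree on the tissue: the growth protocol names stem and the extraction protocol names root. The tissue is therefore not stated as a fact here.

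Per the submitters' processing notes, the values were made with GCRMA, which corrects the background by probe sequence, normalizes across arrays by quantiles and summarises the probes of each probe set, in R 2.6.2. The authors deposited 1 table of log2 values for the 4 arrays. Steps of the authors' processing beyond these names are not given in the sources used here. The deposited log2 values were used as they stand. Medians of the probe sets other than controls lay at 5.97 and 5.98 on the F98902 arrays and at 5.87 and 5.97 on the Cm484 arrays. The number of arrays limits the precision, and low values carry little signal over background.

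Gene names came from the platform's annotation, which is older than the reference table, updated through gene identifiers to the reference table of assembly Zm-B73-REFERENCE-NAM-5.0. Of 17734 probe sets, 1452 had 1 gene, 1 had several, 16281 had none in the table, and 113 were controls, which were left out. The named probe sets stood for 1108 genes, of which 1060 were found in the reference table. Current symbols are mostly identifiers beginning with LOC, so the older gene name is used in the text with that identifier beside it. No genome was used here, and no coordinates are given.

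Probe sets were kept where the value was at or above 5 (log2) on at least 2 of the 4 arrays, which left 10131. The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, F98902 minus Cm484, no covariates, 2 residual and 3.26 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the probe sets kept. "Called" means an adjusted p under 0.05. Unless another test is named, every adjusted p is from this limma fit, and every error beside a log2 difference is its standard error (SE). A probe set under 5 on both arrays of a line has only a bound there, and its fold is given as at least the other line's mean over the value of 5. A probe set's level was never set against that of another probe set.

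Gene lists were written as patterns of gene symbols before the data were examined, and a probe set with 1 gene belonged to a list where its symbol or an older name matched. Lists with 5 or more probe sets kept were tested with limma's camera with a preset correlation of 0.01, adjusted over 12 lists. The list for synthesis of matrix polysaccharides matched no probe set. Symbol patterns also took in names of other kinds of gene. Outside the structural wall list these included PDK1 (LOC541677), a pyruvate dehydrogenase kinase name, in photosynthesis, and GLB1 (LOC541815), a haemoglobin name, in seed and pollen markers. They also included MRP4 (LOC100125659), a transporter name, in root markers, Hb2 (LOC732720) in vascular markers and CDC5 (LOC541962), a splicing-related name, in cell cycle. In auxin response, arf1 (LOC732812) is also an ADP-ribosylation factor name. None of these was called. Further ambiguous matches were sip1 (LOC542299, also named Zlp) in aquaporins, and MRP1 (LOC100037760) and MRP2 (LOC542680) in root markers. Another was cyclotide (LOC606488) in cell cycle. This account of such matches is not complete. Named genes were chosen by a rule fixed before the data were examined: the 10 largest differences in each direction among probe sets called at 2-fold or more, with ranges that do not overlap and with 1 informatively named gene, up to 4 called members of each list by smallest p (or the 2 with the smallest p where none was called), and the classical lignin genes whatever their p. That ranking used the deposited values also where they lie below detection, so it is no order of the folds given as bounds. Other genes named in the text were chosen after their values were seen.

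The steps were tested on simulated data for this comparison, with 200 of the 10131 probe sets changed by known folds on the real means and fitted spreads. Calls with the right sign numbered 5 of 50 at 1.5-fold, 31 of 50 at 2-fold, 49 of 50 at 4-fold and 50 of 50 at 8-fold, with 14 calls among the 9931 unchanged probe sets. The real data gave 3533 calls, far more than were changed here, which loosens the Benjamini-Hochberg cut. The simulated rates therefore do not carry over to the real comparison. Camera called the 1 list of 10 shifted by 2-fold and 0 of 20 unshifted lists. Alternatives changed 1 choice at a time: the filter, quantile normalization or median centring of the deposited values, the variance model, Bonferroni adjustment, averaging the probe sets of a gene, leaving out probe sets of shared sequence (suffixes _s_at, _x_at and _a_at), the replicate number as a block, each array left out over the same probe sets, and camera with an estimated correlation or fry, which tests a list against no change, in place of camera. With an array left out, the lone array of a line was assumed to vary like those of the other line. Camera with an estimated correlation had only 2 residual degrees of freedom, so it could hardly call a list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.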

Results

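Transcript levels were measured on 4 arrays, 2 of the poorly digestible maize inbred F98902 and 2 of the well digestible inbred Cm484. According to the labels, plants grew in a greenhouse at 22 °C by day and 20 °C by night with 14 h of light, and were sampled at flowering, 24 h before ovulation. The comparison asked which transcripts differ between these 2 lines, which the labels describe as of contrasting digestibility. With 1 line of each kind, no difference can be tied to digestibility rather than to any other difference between the lines. The labels give 312.4 and 120.7 ng of RNA for F98902 replicates 1 and 2, and 416.8 and 342.3 ng for Cm484 replicates 1 and 2. Between 54.8% and 55.2% of probe sets reached the detection value of 5 (log2) on each array. The control probe sets set F98902 replicate 2 apart: the median of its 6 probe sets at the 5′ end of maize housekeeping transcripts lay -1.02 (log2) from the mean of the other arrays, while that of the 5 at the 3′ end lay at 0.00. Its added poly-A spike transcripts lay 1.22 above the other arrays.

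The lines differed widely. Of 10131 probe sets kept, 3533 (34.9%) were called, 1797 higher in F98902 and 1736 higher in Cm484. Differences of 2-fold or more were called for 2303 probe sets, 1217 higher in F98902 and 1086 higher in Cm484, and differences of 4-fold or more for 1033. The 2-fold calls included 748 probe sets below detection on both arrays of the other line, 380 with signal in F98902 and 368 with signal in Cm484. Among 748 named genes kept, 271 (36.2%) had a called probe set. Across probe sets kept, the replicate arrays correlated at r = 0.979 in F98902 and 0.982 in Cm484, against 0.765 to 0.790 between arrays of different lines. The first principal component held 91.6% of the variance. The number called was 2205 without Cm484 replicate 1 and 2339 without F98902 replicate 2.

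**Figure D1:**
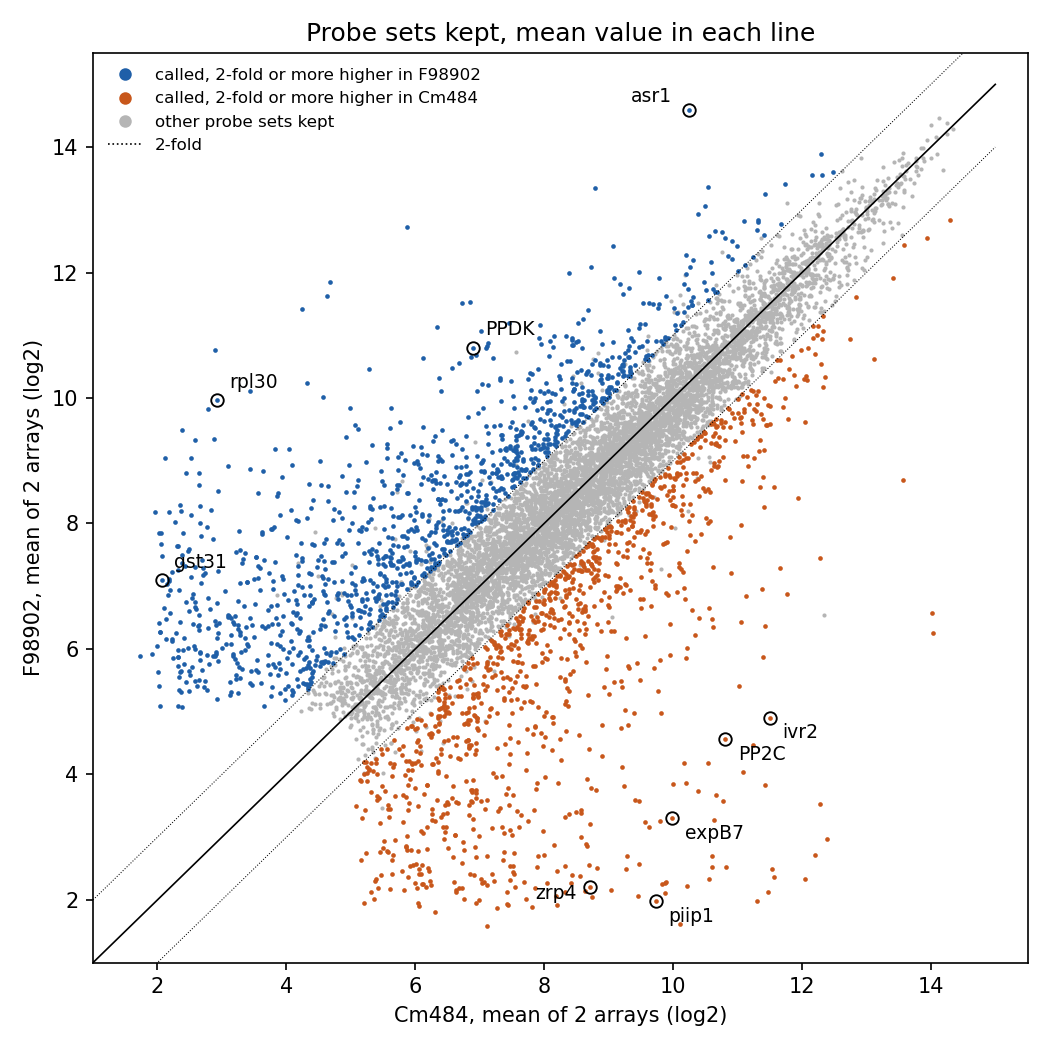
Mean log2 value of each probe set kept in Cm484 (horizontal axis) and F98902 (vertical axis), 2 arrays a line. Blue points are the 1217 probe sets called at 2-fold or more higher in F98902, orange points the 1086 higher in Cm484 and grey points all others, and circles mark 9 named genes, such as rpl30 above and expB7 below the diagonal.

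Among the named genes with higher signal in F98902 was rpl30 (LOC541668), for a protein of the large ribosomal subunit. It stood at 9.96 ± 0.20 (SD, n = 2) in F98902 and below detection in Cm484, at least 31.2-fold apart (adjusted p = 0.00029). The glutathione S-transferase genes gst31 (LOC541842) and gst30 (LOC541841) were at least 4.27-fold and 8.31-fold higher in F98902, and all 4 probe sets of gst31 were called in that direction. asr1 (LOC542304), of the abscisic acid, stress and ripening family, stood at 14.59 ± 0.13 (SD, n = 2) in F98902 against 10.25 ± 1.34 (SD, n = 2) in Cm484 (adjusted p = 0.00501), and no fold is given because its F98902 values are the top of the scale of those arrays. PPDK (LOC542759), the pyruvate orthophosphate dikinase of C4 photosynthesis, was higher in F98902 by 3.91 ± 0.24 (SE, adjusted p = 0.000316). Of its other 3 probe sets, 2 were called in the same direction and the third differed by 0.01. Other named probe sets were below detection in Cm484: piip2 (LOC541647) was at least 5.02-fold higher in F98902, nar at least 4.20-fold, the histone H1 gene his1 (LOC542385) at least 4.18-fold, mfs2 (LOC541978) at least 2.38-fold, and HRGP (LOC542371), a hydroxyproline-rich glycoprotein of the wall, at least 1.92-fold. F98902 replicates 1 and 2 read 6.47 and 7.68 for nar and 6.04 and 8.09 for his1, so these bounds depend on the array. A second probe set of his1 was detected in both lines, with a difference of -0.50 (adjusted p = 0.465), and the call of the first was lost without Cm484 replicate 1.

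In the other direction, 3 named genes were beta-expansins, proteins that loosen the cell wall. expB7 (LOC542649) was at least 31.8-fold, expB6 (LOC542566) at least 14.9-fold and expB8 (LOC542496) at least 7.88-fold higher in Cm484, each from a probe set below detection in F98902. That of expB8 read 8.63 and 7.32 on Cm484 replicates 1 and 2, so its bound depends on the array. A second probe set of expB8 reached detection on 1 F98902 array, with a mean under the detection value, and was higher in Cm484 (adjusted p = 0.0286). The acid invertase gene ivr2 (LOC542324), whose enzyme splits sucrose in the vacuole, stood at 11.51 ± 1.09 (SD, n = 2) in Cm484 and 4.91 ± 0.19 (SD, n = 2) in F98902 (adjusted p = 0.000671), where its mean lies under the detection value, so no exact fold is given. PP2C (LOC542176), a protein phosphatase gene, was at least 56.1-fold higher in Cm484, although its other probe set gave -0.99. Root-preferential zrp4 (LOC542706), which resembles O-methyltransferases, was at least 13.1-fold higher, the MADS-box gene zmm24 (LOC542038) at least 21.4-fold, gst41 (LOC541849) at least 10.0-fold and gar2 (LOC541620) at least 4.81-fold. The bound for gar2 depends on the array, with 7.99 and 6.54 on Cm484 replicates 1 and 2. piip1 (LOC542597) was at least 26.7-fold higher in Cm484, where its replicates read 12.09 and 7.39. Its adjusted p was 0.0131, the call was lost with either F98902 array left out, and all 4 of its probe sets were called in that direction, the weakest at -0.55 ± 0.15 (SE, adjusted p = 0.0445).

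**Figure D2:**
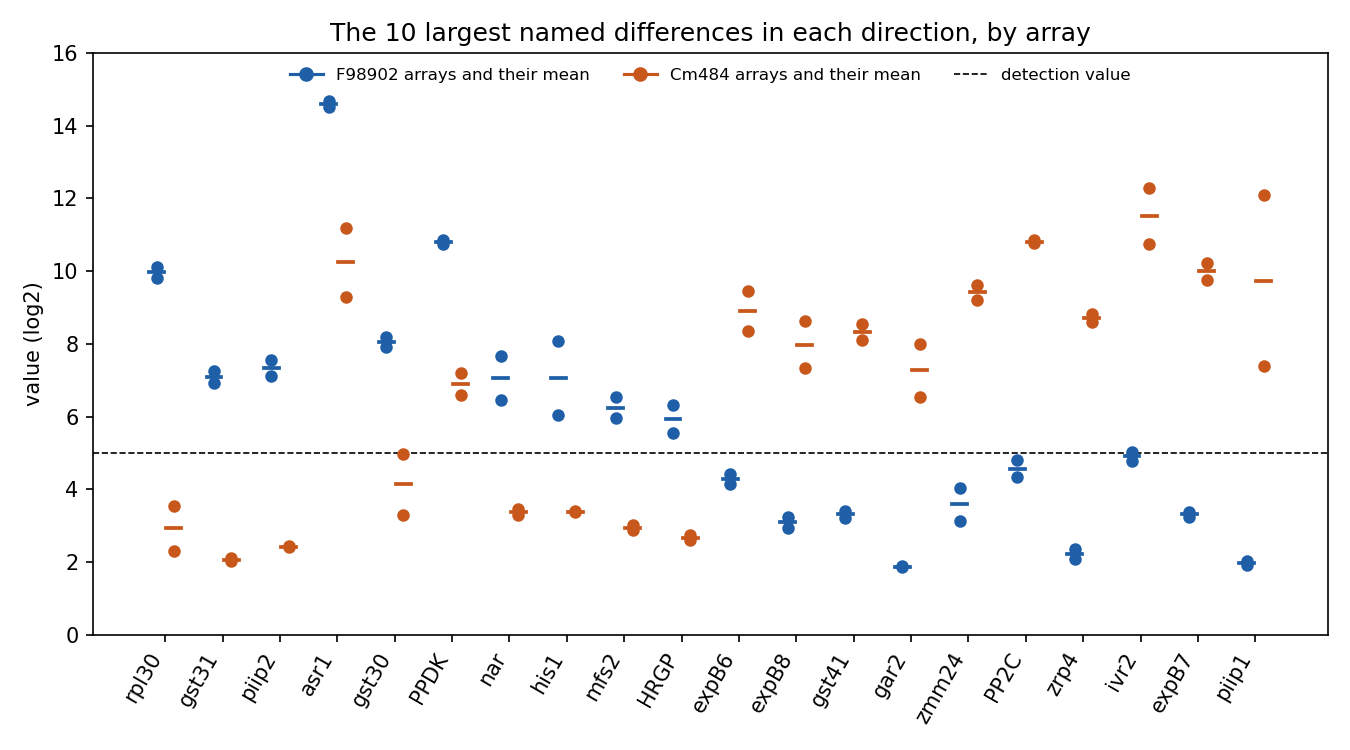
Log2 value on each array (points) and line mean (bars) for 10 named genes in each direction, ranked by the deposited values, F98902 in blue and Cm484 in orange, with the detection value of 5 dashed. For many of these genes the 2 arrays of a line lie more than 2-fold apart, such as asr1 (11.19 and 9.30 in Cm484) and his1 (6.04 and 8.09 in F98902). The widest gap between replicates is that of piip1, at 12.09 and 7.39 in Cm484. Of all probe sets kept, 2.73% differed by 2-fold or more between the F98902 arrays and 2.68% between the Cm484 arrays.

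None of the monolignol genes that the annotation names and the filter kept was called. The 4 probe sets kept gave small differences: -0.43 ± 0.17 (SE) for the cinnamoyl-CoA reductase gene CCR (LOC542463, adjusted p = 0.107), -0.36 ± 0.15 for the cinnamyl alcohol dehydrogenase gene bm1 (LOC542663, adjusted p = 0.13), -0.30 ± 0.17 for the phenylalanine ammonia-lyase gene PAL1 (LOC542258, adjusted p = 0.225) and -0.09 ± 0.15 for 4CL (LOC542166, adjusted p = 0.683). Adjusted over the list alone, 0 of the 4 were called. A second reductase gene, ccr2 (LOC542735), was below detection on all 4 arrays. Other classical lignin genes, such as bm3, had no probe set that the annotation names, so any probe sets for them were tested without a name. With 2 arrays a line, differences as small as these may go uncalled, and the 4 probe sets do not stand for the whole pathway. Around this pathway, the peroxidase PER42 was higher in F98902 by 0.96 ± 0.16 (SE, adjusted p = 0.00842), 1 of 2 kept members of its list. myb31 (LOC100037768), a MYB factor known to repress lignin genes, was higher in F98902 by 0.83 ± 0.21 (SE, adjusted p = 0.0313), 1 of 3 MYB and NAC members, a call lost with no filter and without F98902 replicate 2, Cm484 replicate 1 or Cm484 replicate 2. Both counts were unchanged when adjusted over the list alone. The chalcone synthase gene chs1 (LOC541645) was 3.37-fold higher in F98902 (adjusted p = 0.00123), 1 of 2 flavonoid members called, or 2 when adjusted over the list alone or without F98902 replicate 2.

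Wall loosening genes stood out among the wall lists. All 6 probe sets kept, for 5 genes, were higher in Cm484, also when adjusted over the list alone, with a median difference of -4.36, or -3.48 with the 3 probe sets below detection in F98902 at their bound. They were expB7, expB6, expB8, the alpha-expansin expa1 (LOC541904, -4.11 ± 0.83 SE, adjusted p = 0.0166), which read 11.66 and 9.02 on Cm484 replicates 1 and 2, and the xyloglucan endotransglycosylase xet1 (LOC542312, -0.85 ± 0.16 SE, adjusted p = 0.012, not called without Cm484 replicate 2). The median log2 difference of wall loosening and remodelling was -3.43 without Cm484 replicate 1 and -5.29 without Cm484 replicate 2. The list shifted against all other probe sets (camera adjusted p = 0.000914; adjusted p = 0.553 with an estimated correlation). The 3 probe sets below detection in F98902 passed the filter through Cm484 alone, so only a higher value in Cm484 was possible for them. The array has 20 probe sets for this list, and with no filter the gene list shift of wall loosening and remodelling had a camera adjusted p of 0.0893. Of the cellulose synthesis list, which holds cellulose synthase genes and the brittle stalk gene bk2 (LOC778435), cesa3 (LOC542489, -0.89 ± 0.17 SE, adjusted p = 0.0151) and cesa5 (LOC541803, -0.69 ± 0.20 SE, adjusted p = 0.0468) were higher in Cm484, while the other 12 of 14 probe sets were not called. Neither cesa gene was called without F98902 replicate 1, F98902 replicate 2 or Cm484 replicate 2, and cesa5 was also lost with no filter or quantile normalization. Adjusted over the list alone, 1 was called, and the list did not shift (camera adjusted p = 0.19).

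Among structural wall proteins, 4 of 7 probe sets were higher in F98902 and 0 in Cm484, and 4 were called when adjusted over the list alone. The list shifted (camera adjusted p = 0.0185; adjusted p = 0.553 with an estimated correlation), with a median of 0.53. Of the 4, HRGP is a wall glycoprotein and GRP (LOC542562, 0.53 ± 0.15 SE, adjusted p = 0.0489) a glycine-rich protein, whose call was lost whichever array was left out. Agpsemzm (LOC542072, 1.03 ± 0.15 SE, adjusted p = 0.00601) is a name for a subunit of ADP-glucose pyrophosphorylase, a starch enzyme, which shares the symbol AGP with arabinogalactan proteins, and AGP2 (LOC542737, 2.20 ± 0.30 SE, adjusted p = 0.00448) carries the same ambiguous symbol. Without AGP2, Agpsemzm, PRP (LOC542467, also a splicing factor name) and GRP (whose place in the cell is not given), a choice made after seeing the data, fewer than 5 probe sets remained and the list could not be tested.

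Aquaporins, the channels for water and small solutes, were higher in Cm484 for 14 of 24 probe sets (13 genes), higher in F98902 for 4 (2 genes) and not called for 6. The same 18 calls came when adjusted over the list alone. The plasma membrane genes ZmPIP2-2 (LOC542644) and ZmPIP2-3 (LOC541889) were at least 5.53-fold and 13-fold higher in Cm484, and NIP3-1 (LOC541885) was 6.92-fold higher (-2.79 ± 0.15 SE, adjusted p = 0.000227). Against this direction, the tonoplast gene TIP4-1 (LOC541897) was 5.65-fold higher in F98902 (2.50 ± 0.16 SE, adjusted p = 0.000368). The list median was -1.20 (camera adjusted p = 0.00847; adjusted p = 0.553 with an estimated correlation).

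Photosynthesis genes went the other way. Of 18 probe sets (12 genes), 11 (7 genes) were higher in F98902, 1 was higher in Cm484 and 6 were not called; adjusted over the list alone, 13 were called. The uncalled include 2 probe sets of PDK1 (LOC541677), a pyruvate dehydrogenase kinase name matched by its symbol. Besides PPDK, the calls included psad1 (LOC541791, a photosystem I subunit, 2.30 ± 0.18 SE, adjusted p = 0.000742) and the light-harvesting genes Lhcb5-2 (LOC542320, 1.58 ± 0.16 SE, adjusted p = 0.00163) and lhcb6 (LOC542321, 1.19 ± 0.17 SE, adjusted p = 0.00506). The exception was lhcb5 (LOC542716), at -0.94 ± 0.19 (SE, adjusted p = 0.0167). The list median was 1.17 (camera adjusted p = 0.000633; adjusted p = 0.619 with an estimated correlation).

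**Figure D3:**
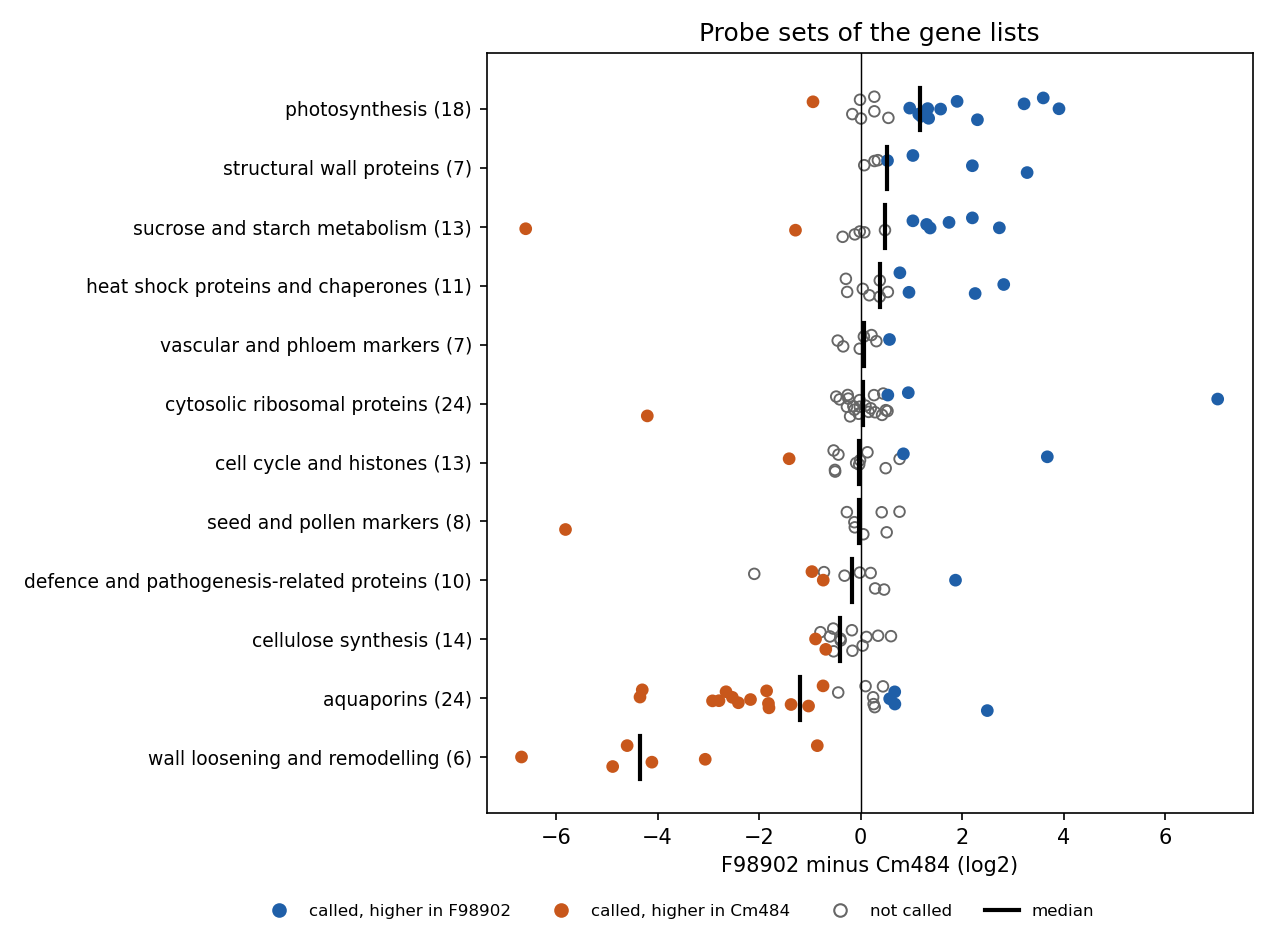
Log2 difference, F98902 minus Cm484, of each probe set kept (points, jittered vertically) in the 12 lists with 5 or more probe sets, whose numbers are in parentheses; filled points are called and vertical bars are list medians. Wall loosening has all 6 points left of 0 and a median of -4.36, and photosynthesis has a median of 1.17.

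Sucrose and starch genes were called in both directions, 6 of 13 higher in F98902 and 2 higher in Cm484, and 9 were called when adjusted over the list alone (camera adjusted p = 0.19). ivr2 and the starch branching enzyme gene ae1 (LOC542238, -1.28 ± 0.20 SE, adjusted p = 0.0077) were higher in Cm484, whereas another such gene, sbe1 (LOC542315, 2.73 ± 0.28 SE, adjusted p = 0.00187), the ADP-glucose pyrophosphorylase gene GLG1 (1.74 ± 0.15 SE, adjusted p = 0.000997) and the cell wall invertase gene incw1 (LOC542314, 1.30 ± 0.17 SE, adjusted p = 0.00417) were higher in F98902. AGP2 and Agpsemzm are 2 of the 6, counted here and among structural wall proteins. The list mean of 0.20 lay below its median of 0.48 because of ivr2.

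Of the stress lists, 4 of 11 heat shock probe sets were higher in F98902 and 0 in Cm484, with the same count adjusted over the list alone (camera adjusted p = 0.0776). hsp22 (LOC542602) was at least 2.25-fold higher, hsp18a (LOC542293) 4.78-fold (adjusted p = 0.00383), hsp101 (LOC541780) 1.94-fold (adjusted p = 0.0234) and hsp70-5 1.71-fold (adjusted p = 0.0148), whose other 2 probe sets were not called (1.45-fold, adjusted p = 0.0825, and 1.30-fold, adjusted p = 0.224). The call of hsp70-5 was lost whichever array was left out and that of hsp101 without F98902 replicate 2, Cm484 replicate 1 or Cm484 replicate 2, which left 2 heat shock calls in each of those 3 cases. All 4 dehydration and abscisic acid probe sets were called, also when adjusted over the list alone. Those of the dehydrin dhn2 (LOC542251) were higher in F98902, by 4.01-fold for the clearest (adjusted p = 0.00378), and vp14 (LOC732819), a gene of abscisic acid synthesis, was higher in Cm484 (-1.34 ± 0.31 SE, adjusted p = 0.0246). Of these 4 calls, 1 remained without Cm484 replicate 1 or with no filter, and 2 with either F98902 array left out. Defence genes gave 3 calls of 10, also when adjusted over the list alone: lox1, a lipoxygenase gene, at -0.96 ± 0.17 (SE, adjusted p = 0.0105) and a second probe set of it at -0.74, and pr5 (LOC542720) at 1.87 ± 0.35 (SE, adjusted p = 0.0129). With either Cm484 array left out, 1 of these calls remained, and the list did not shift (camera adjusted p = 0.857). In the wax and cuticle list, plt2 (LOC542343), a phospholipid transfer protein gene, was 6.95-fold higher in Cm484 (adjusted p = 0.0182), 1 of 2 members by either adjustment and not called with no filter or with either F98902 array left out. On Cm484 replicates 1 and 2, plt2 read 9.31 and 7.49, against 5.53 and 5.67 on the F98902 arrays. Neither auxin response member was called by either adjustment, with -0.22 ± 0.16 (SE, adjusted p = 0.34) for arf1 (LOC732812), also a name of an ADP-ribosylation factor, and 0.00 ± 0.15 (SE, adjusted p = 0.991) for abp1 (LOC542232).

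Markers of tissues and cell states moved singly. Of 3 root markers kept out of 16, zrp4 alone was called, by either adjustment. Among 8 seed and pollen markers kept out of 41, zmm24 alone was called, by either adjustment, with 2 calls without F98902 replicate 2 (camera adjusted p = 0.942). The phloem potassium channel gene ZMK2 (LOC542002, 0.56 ± 0.16 SE, adjusted p = 0.044) was the single call among 7 vascular markers, and 0 were called when adjusted over the list alone or with any array left out (camera adjusted p = 0.942). In the cell cycle and histone list, 3 of 13 were called, or 2 when adjusted over the list alone and 1 with no filter or without probe sets of shared sequence: pcna2 (LOC542357), a replication factor, at -1.41 ± 0.22 (SE, adjusted p = 0.00712), his1, and the centromeric histone gene cenH3 (LOC542500), at least 1.22-fold higher in F98902 but not called without F98902 replicate 2, Cm484 replicate 1 or Cm484 replicate 2 (camera adjusted p = 0.974). Ribosomal protein genes gave 4 calls of 24, or 3 when adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.748). rps21b (LOC542449) was 18.4-fold higher in Cm484 (-4.20 ± 0.18 SE, adjusted p = 0.000131), opposite to rpl30, while rpl29 (LOC541790) and rps27 (LOC542617) were higher in F98902 by 0.94 ± 0.16 (SE, adjusted p = 0.00922) and 0.54 ± 0.16 (SE, adjusted p = 0.0497), the latter not called with any array left out.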

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

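All tests of explanations in this part were chosen after the results were seen. The control probe sets, which entered no comparison, held a signal that differed between arrays. On F98902 replicate 2, which the labels give the least RNA (120.7 ng), the added poly-A spikes lay 1.22 (log2) above the mean of the other arrays and the 5′ probe sets of maize housekeeping transcripts lay -1.02 from it.

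The first pattern weighed is the very large differences at single genes. A change of ribosomal protein transcripts together is argued against: rpl30 and rps21b went opposite ways, and the other 22 ribosomal probe sets had a median difference of 0.0401 (quartiles -0.19 and 0.39). A sequence difference between the lines under the oligonucleotides of 1 probe set remains open. Among probe sets with signal in both lines, 6 genes had a called difference of 4-fold or more and a further probe set under another cluster or subcluster number. For PPDK, dhn2 and LOC542643 only the subcluster number differed, so those probe sets may overlap in sequence. The further probe sets showed on average 0.359 of the difference (95% bootstrap interval -0.0282 to 0.677), from -0.506 for PLTP, where the direction turned, to 0.953 for LOC542643. This interval includes 0.5, the value set to decide, so a sequence difference and a difference in transcript level between the lines, the biological explanation, cannot be told apart for these genes as a set, and genes below detection in 1 line were not tested.

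The second pattern is the higher signal of wall loosening and aquaporin genes in Cm484. Lower RNA quality on F98902 replicate 2, if present, is argued against as the explanation. The median of the 30 probe sets was -1.81 with all arrays and -1.79 without that array. Growth stage or position that differs between samples is a candidate explanation for part of the wall loosening difference: Cm484 replicate 1 exceeded replicate 2 by a median of 1.199 over the 6 probe sets, outside the range of -0.37 to 0.22 that held 95% of 10000 random lists matched on mean value. For the 24 aquaporin probe sets the same value was 0.0351, inside the range of -0.18 to 0.08, which decides nothing, since a stage or position shared by both Cm484 samples would leave no gap between them. A difference between the lines stays open as the biological explanation and was not tested.

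The third pattern is the higher signal of photosynthesis genes in F98902. F98902 replicate 2, the array with the lower 5′ control signal, does not account for it. The median of 16 probe sets, PDK1 left out, was 1.26 with all arrays and 1.39 without that array. Over the 11 genes the SD was 5.49 times the median SE, with gene means from -0.94 to 2.68. This spread cannot decide on a larger share of green tissue as the only cause. How far such a share would move each gene depends on its level in the other tissue, which was not measured. A difference in tissue makeup, line differences of single genes, or both together stay open.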

How the results depend on the processing

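Of 55 called named probe sets, 0 turned direction under any alternative, which says little on stability. A change of filter, variance model or adjustment leaves a log2 difference as it is. Leaving out an array cannot turn a probe set whose ranges do not overlap. Of the 55, 16 lost their call when 1 array was left out and 13 under another alternative besides Bonferroni. Bonferroni adjustment left 235 probe sets that differ between the lines, 112 higher in F98902 and 123 higher in Cm484, and the same 235 of 2-fold or more. With 1 array left out, the number of probe sets that differ ranged from 2205 (without Cm484 replicate 1) to 2706, with 2339 without F98902 replicate 2. The probe sets that differ between the lines, higher in Cm484, ranged from 1082 to 1371 (1082 without Cm484 replicate 1, 1128 without F98902 replicate 2, 1122 without Cm484 replicate 2) and the probe sets that differ between the lines, higher in F98902, from 1123 (without Cm484 replicate 1) to 1426. With no filter, replicate agreement was r = 0.994 in Cm484 and 0.992 in F98902, and 0.937 to 0.946 between lines (0.942 and 0.946 for F98902 replicate 1, 0.937 and 0.940 for replicate 2, against Cm484 replicates 1 and 2).

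With the replicate number as a block, 2983 probe sets were called; replicate numbers are shared in the labels only, and the deviations of equally numbered arrays correlated at -0.024, so they were not treated as pairs. Fewer arrays or a stricter adjustment lowered the counts above by construction, and the causes of the other changes were not tested. Below the detection value of 5, signal over background limits what a difference means.

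The 4 gene list shifts became 0 with an estimated correlation: adjusted p = 0.553 for aquaporins, structural wall proteins and wall loosening, and 0.619 for photosynthesis. Over the camera alternatives the adjusted p ranged from 0.00433 to 0.553 for the gene list shift of structural wall proteins, with 0.0546 at a filter of 7, 0.0741 by Bonferroni and a range of 0.0138 to 0.0583 with 1 array left out (highest without Cm484 replicate 2). The gene list shift of wall loosening and remodelling had 0.0893 with no filter, within a range up to 0.553. The gene list shift of heat shock proteins and chaperones had 0.0256 to 0.183 with 1 array left out (0.0256 without F98902 replicate 1, 0.0482 without Cm484 replicate 1), within a camera range up to 0.619. Fry tests a list against no change, not against the other probe sets, so its values are no shift: its directional form gave 0.0494 for heat shock and 0.0429 for seed and pollen markers. Mixed fry, which counts changes in either direction, called all 12 lists tested. Its adjusted p was 0.00358 for cell cycle and histones, 0.00702 for cellulose synthesis, 0.0042 for ribosomal proteins, defence, heat shock and sucrose and starch, 0.00521 for seed and pollen and 0.0275 for vascular markers. With 34.9% of all probe sets kept called, most lists hold some change, so these values set no list apart. Counts of called list members that left-out arrays moved by more than 1.5 times stand in the report. With no filter, his1, cenH3, hsp101, myb31, piip1, plt2, pr5, vp14 and cesa5 lost their calls. Without probe sets of shared sequence, 10 aquaporin, 7 photosynthesis, 1 cell cycle and 1 dehydration probe sets were called, and a filter of 7 left 2 heat shock and 0 cell cycle calls; Bonferroni left at most 1 called probe set in each list. Leaving out members of ambiguous symbol and testing probe sets with 1 gene alone were chosen after seeing the data; the former left too few structural wall members for a test.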

Other observations

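The gene families below were chosen after the values were seen, by symbol, and none was tested as a list. Glutathione S-transferases, which conjugate glutathione to foreign and reactive compounds, differed in both directions: of 16 probe sets (13 genes), 7 were higher in F98902, 4 of them of gst31, and 2 in Cm484, which makes 4 genes against 2. Besides those already named, gst10 (LOC541828) was at least 2.06-fold higher in F98902 (adjusted p = 0.0114) and GST38 (LOC541847) at least 3.07-fold higher in Cm484 (adjusted p = 0.00149). Of 15 probe sets for cytokinin signalling, 3 response regulators were higher in F98902, among them RR6 (LOC541632, 2.95 ± 0.32 SE, adjusted p = 0.00214) and RR11 (LOC541613, 2.14 ± 0.27 SE, adjusted p = 0.0035), while RR7 (LOC541633, -1.05 ± 0.26 SE, adjusted p = 0.032) and the receptor gene hk3 (LOC541642, -1.15 ± 0.15 SE, adjusted p = 0.00424) were higher in Cm484.

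Of 5 glutamine synthetase genes, which assimilate ammonium, 2 were higher in Cm484 and 0 in F98902: gln3 (LOC542215) was at least 9.47-fold higher (adjusted p = 0.000116) and gln2 (LOC542400, -1.99 ± 0.17 SE, adjusted p = 0.000869) 3.97-fold. Tubulin genes gave 5 calls of 16 probe sets, 4 of them higher in Cm484, led by tub4 (LOC542417, -2.03 ± 0.24 SE, adjusted p = 0.00281), with TUBB2 in the opposite direction at 1.26 ± 0.27 (SE, adjusted p = 0.019).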
